A study of Bos taurus with 8 samples.

How the data were processed

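RNA from primary bovine granulosa cells, the somatic cells that surround the oocyte and make oestradiol and progesterone, was measured on 8 expression arrays. Per the labels' protocols, the cells grew in serum-free alpha-MEM with follicle-stimulating hormone, insulin-like growth factor 1 and androstenedione. The medium was exchanged on day 2 and day 4 for medium holding either bovine serum albumin alone (BSA, 4 arrays) or a mix of non-esterified fatty acids (NEFA, 4 arrays), and cells were harvested on day 6. The composition and dose of the fatty acid mix are not given in the sources used here. Per the labels' protocols, total RNA was extracted on silica columns and labelled with biotin after the array maker's standard method.

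The deposited values are log2 expression values that the authors obtained with RMA, per the submitters' processing notes. RMA corrects the background, makes the distributions of the arrays equal and summarises the probes of a probe set into 1 value. The software, its version, the probe annotation and the genome build are not given in the sources used here. The table held 24415 probe sets with 2 decimals each. The values ran from 0.64 to 13.49, and array medians from 4.78 to 4.86. Because RMA forces similar distributions, a change shared by all transcripts could not be seen, and small folds of dim probe sets are understated. Arrays give no read depth, and the number of arrays limits the precision.

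Probe sets were named through the platform annotation supplied with the data, with symbols updated by gene ID through a RefSeq gene table (assembly ARS-UCD2.0), which matched 17996 symbols. Of the probe sets, 18457 had 1 gene symbol, 688 had several and 5270 had none; only those with 1 symbol were named. They stood for 18010 genes, of which 401 had more than 1 probe set, and the brightest probe set over all 8 arrays stood for its gene. Array controls could not be told from unnamed probe sets, so all probe sets were tested. No coordinates are given, since the build behind the annotation is not stated.

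The groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with default settings) on the deposited values, as NEFA minus BSA without further normalization. The p-values were adjusted by Benjamini-Hochberg over all probe sets, and the threshold was 0.05. Gene lists were tested on the gene-level table with camera, a limma test that compares a list with all other genes, with a preset correlation of 0.01 between genes. The camera p-values were adjusted by Benjamini-Hochberg over the 27 lists. Camera with a correlation estimated for each list, and fry, which asks whether a list's genes move one way on balance, were run as alternatives. The same member tests were also adjusted over the list alone. The 19 pathway lists and 8 lists of markers of other cells held 510 genes. Of these, 457 could be matched to a measured gene, and 23 genes were in more than 1 list. The lists, the tests, the alternatives and the rule for naming genes were set before the data were examined.

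The rule named the 15 largest rises and 15 largest falls among genes past the threshold whose groups did not overlap. It further took up to 4 members of each list with the largest changes past the threshold, or the member with the smallest p where none passed, and 20 genes of lipid metabolism and granulosa function in any case. Of those 20, 17 were measured, and the others are not reported here. In all, 80 genes were named, and 2 of them (HADHA and LGALS9) had a second probe set that differed in call or direction. The few other genes named below were chosen after their values were seen. In the Results they are HADHB, LPCAT3, NPC2, APOE, HSD17B1, IRF7, ISG15, RIGI and LAMB1. Further on they are the leukocyte markers given with their levels and the genes named only under the other observations.

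The test was tried on simulated data for this comparison, with 24415 probe sets and the real means and spreads. It recovered 1 of 50 simulated changes of 0.25 on the log2 scale, 26 of 50 at 0.5, 41 of 50 at 1 and 49 of 50 at 2. Of its 123 calls, 6 were false. With 18010 simulated genes, camera called the list shifted by 0.3 and 0 of the 26 other lists. The simulated genes were drawn independently of each other, so this does not test camera on lists whose members vary together.

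The alternatives were the replicate number as a block, a further quantile normalization, centring of each array on its median, leaving out the dimmest 33.3% of probe sets, eBayes with trend and robust settings, array weights, the mean of a gene's probe sets, a linear model without moderation, a log2 change of at least 1 as a further criterion, and leaving out each array in turn. Counts and ranges over alternatives given with a result leave out the replicate block, whose effect is given once with the other settings. An extracellular matrix list without stromal markers was added after seeing the data. The counts were also taken for all 35 splits of the 8 arrays into 4 and 4, the real one included. No pair of arrays held more than 2.78% equal values, so no array was counted more than once.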

Results

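The transcriptome of bovine granulosa cells was compared between cultures given a mix of non-esterified fatty acids (NEFA) and cultures given the carrier protein alone (BSA), with 4 arrays in each group. Non-esterified fatty acids are released from fat stores, and the comparison asks which transcripts differ in granulosa cells exposed to them. Levels are given on the log2 scale as mean ± SD of the 4 arrays of a group (SD, n = 4), and changes are NEFA minus BSA with the standard error (SE) of limma. The labels do not say whether the replicates are separate animals, pools or cultures, so p-values measure only the spread between these samples, which may be technical.

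With NEFA, 5 of 24 measured fatty acid oxidation genes rose and 11 of 19 fatty acid synthesis genes fell. ANGPTL4 (an inhibitor of lipoprotein lipase) rose 8.85-fold, the fatty acid transporter CD36 6.86-fold and PDK4, a kinase that restrains pyruvate oxidation, 4.11-fold. FASN, the fatty acid synthase, fell by 1.11 on the log2 scale and ABCA1, a cholesterol exporter, fell by 1.10. A set of interferon-induced genes rose as well, among them OAS1Y, IFI27, MX1 and IFI6. In all, 423 of 18010 genes passed the limma threshold, 180 of them higher and 243 lower with NEFA. Counted as probe sets, 217 were higher and 278 lower of 24415. Most changes were small: the median absolute log2 change of the changed genes was 0.43, and 24 rose and 5 fell by at least 1. The groups did not overlap for any of the 423 changed genes, which the threshold largely brings about with 4 arrays in each group. Over all genes, 12.4% showed no overlap, where chance gives 2.86%. Centring each array on its median gave 127 genes higher and 302 lower, so the higher share went from 42.6% to 29.6%. The array medians differed by 0.035 between the groups, but the median change over all genes was 0.005 without centring. The centred counts are thus not plainly the better ones. The count depended on the number of arrays. Without BSA 1, 2, 3 and 4 in turn it was 237, 164, 188 and 210 genes, and without NEFA 1, 2, 3 and 4 it was 169, 168, 198 and 260.

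The arrays of a group resembled each other more than those of the other group. Pearson correlations across probe sets, which are not independent, ran from 0.9935 to 0.9948 within groups and from 0.9914 to 0.9935 between them. The first principal component held 26.0% of the variance and placed all BSA arrays on one side and all NEFA arrays on the other; the next held 15.1%.

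Some genes of fatty acid metabolism rose with NEFA, among them some that carry fatty acids into mitochondria and oxidise them. ANGPTL4, CD36 and PDK4, given first, are not in the fatty acid oxidation list. ANGPTL4 (probe set 12878460) went from 4.17 ± 0.16 to 7.32 ± 0.08 (SD, n = 4; limma, Benjamini-Hochberg adjusted p = 1.99e-06), and CD36 (probe set 12852910) from 6.62 ± 0.14 to 9.40 ± 0.08, with the same adjusted p. PDK4 went from 5.16 ± 0.27 to 7.20 ± 0.22. The gatekeepers of mitochondrial entry, CPT1A and CPT1B, rose by 1.11 (SE 0.056) and 1.17 (SE 0.081). The carnitine carrier SLC25A20 rose by 0.75, and HADHA and HADHB, the subunits of the trifunctional protein, rose by 0.74 and 0.69. For HADHA a second, dim probe set (mean level 1.77) changed by -0.01 and did not pass. Of the 24 measured fatty acid oxidation genes, 5 rose, none fell and 19 did not pass; adjusted over the list alone 8 rose. The list as a whole was higher, with a median change of 0.07, or 0.04 without BSA 3 (camera, adjusted p = 2.48e-05; adjusted p = 0.092 with an estimated correlation).

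Targets of the fatty acid receptor PPAR followed the same members. Of 20 measured, 7 rose (ANGPTL4, CD36, PDK4, CPT1A, PLIN2, SLC25A20 and HADHA), 1 fell and 12 did not pass, with a median change of 0.14; adjusted over the list alone 8 rose and 1 fell. The list passed with the preset correlation (camera, adjusted p = 2.49e-10) and with an estimated one (adjusted p = 0.0061 with an estimated correlation). The exception was FABP3, the heart-type fatty acid binding protein, which fell by 1.10 (8.99 ± 0.08 to 7.89 ± 0.15). Of the 16 uptake and activation genes, CD36, SLC27A1 and FABP5 rose by 2.78, 0.76 and 0.55, FABP3 fell and 12 did not pass; adjusted over the list alone 4 rose and 2 fell. Its median change was -0.02 and its mean 0.17, with the test on the side of the mean (camera, adjusted p = 0.41). Of 26 lipid droplet and triacylglycerol genes, PLIN2, which coats lipid droplets, rose by 1.10 (9.49 ± 0.04 to 10.59 ± 0.02), PLIN4 rose by 0.34 and LPIN1, a phosphatidate phosphatase, fell by 0.44; 23 did not pass, and adjusted over the list alone 4 rose and 1 fell. The median change was 0.07, or 0.04 without BSA 3 and 0.03 without BSA 4, and the list did not pass (camera, adjusted p = 0.066), though it did in 4 of 16 alternatives other than the replicate block (adjusted p from 9.91e-04 with fry to 0.22). The uptake list passed with fry alone (adjusted p = 9.93e-04). The calls of FABP5 and PLIN4 ended without 6 and 7 of the 8 arrays, at adjusted p up to 0.069 without NEFA 1 and 0.085 without NEFA 1 (limma), and that of PLIN4 also with trend and robust eBayes (adjusted p = 0.057).

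**Figure D1:**
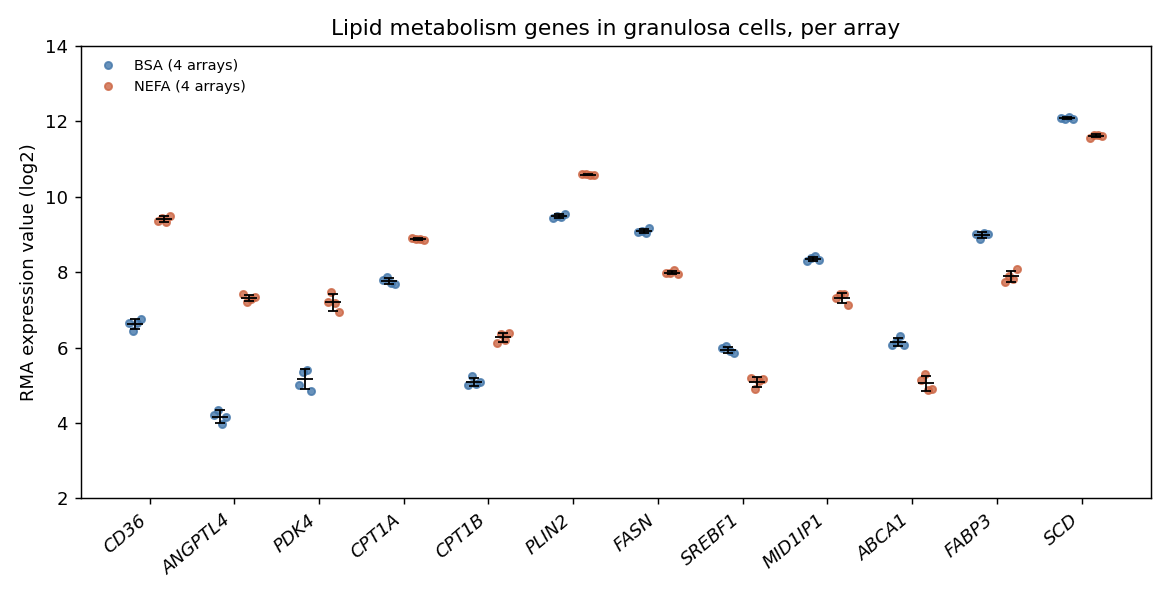
Log2 expression of 12 lipid metabolism genes on each of 8 arrays (points: BSA blue, NEFA orange); the black marks give the mean and SD of the 4 arrays of a group. ANGPTL4 rose from 4.17 to 7.32 and CD36 from 6.62 to 9.40, while FASN fell from 9.10 to 7.99 and ABCA1 from 6.15 to 5.05.

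Many fatty acid synthesis genes and some cholesterol synthesis genes fell. FASN went from 9.10 ± 0.06 to 7.99 ± 0.04 (limma, Benjamini-Hochberg adjusted p = 6.67e-05), and MID1IP1, which activates acetyl-CoA carboxylase, from 8.35 ± 0.06 to 7.32 ± 0.13. SREBF1, the transcription factor that drives these genes, went from 5.95 ± 0.08 to 5.09 ± 0.13. ACSS2, which makes acetyl-CoA from acetate, fell by 0.70 on the log2 scale, and SCD, the stearoyl-CoA desaturase, fell by 0.46. Of 19 fatty acid synthesis genes, 11 fell, none rose and 8 did not pass; adjusted over the list alone 12 fell. The list was lower, with a median change of -0.28 (camera, adjusted p = 5.08e-12; adjusted p = 0.0061 with an estimated correlation).

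Of 17 cholesterol synthesis and uptake genes, TM7SF2, DHCR7, LSS and INSIG1 fell by 0.62, 0.39, 0.39 and 0.30 on the log2 scale, 13 did not pass and none rose; adjusted over the list alone 11 fell. The median change was -0.18, with lower values for 17 of 17 (camera, adjusted p = 2.49e-10; adjusted p = 0.089 with an estimated correlation). Of 12 genes in the list of LXR targets and sterol export, ABCA1, SREBF1, MYLIP, SCD, LPCAT3 and NPC2 fell, APOE rose by 0.36 and 5 did not pass; adjusted over the list alone 6 fell and 2 rose. The largest fall was that of ABCA1, from 6.15 ± 0.11 to 5.05 ± 0.21, and MYLIP, a ubiquitin ligase, fell by 0.78. The list was lower, with a median change of -0.24 (camera, adjusted p = 3.51e-04; adjusted p = 0.089 with an estimated correlation). The calls of INSIG1, LSS and MYLIP ended without 4, 3 and 2 of the arrays, at adjusted p of at most 0.057 for INSIG1 and LSS without NEFA 2 and 0.056 for MYLIP without BSA 2 (limma).

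Few genes that define granulosa cells and their hormone production passed the limma threshold. CYP19A1, the aromatase that makes oestradiol, was 7.52 ± 0.18 with BSA and 8.02 ± 0.32 with NEFA, which did not pass (limma, adjusted p = 0.17; 95% interval of the change 0.14 to 0.87). HSD17B1, a steroid dehydrogenase chosen after its value was seen, was 1.68-fold lower and did not pass either (limma, adjusted p = 0.12). CYP11A1, which makes pregnenolone from cholesterol, changed by -0.12 (adjusted p = 0.28, limma) and SCARB1, a receptor for cholesterol-carrying lipoprotein, by -0.22 (adjusted p = 0.052, limma). SCARB1 passed in 4 of its 14 alternative settings other than the replicate block (limma, adjusted p from 1.63e-04 to 0.13) and CYP11A1 in 1, with trend and robust eBayes (adjusted p from 0.022 to 0.44). Of 14 steroid hormone synthesis genes 0 passed in limma (2 higher and 7 lower at an unadjusted p under 0.05); adjusted over the list alone 6 fell and 1 rose. The list passed as lower, with a median change of -0.12 (camera, adjusted p = 0.0061; adjusted p = 0.14 with an estimated correlation). FSHR, LHCGR, FOXL2 and CCND2 changed by 0.17, 0.03, -0.04 and 0.10, none of which passed (limma). LHCGR was dim, at 2.70 with BSA and 2.73 with NEFA, so its small change says little.

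Of 27 granulosa identity and FSH response genes, CITED1, a transcriptional coactivator, fell by 0.72 (8.01 ± 0.05 to 7.29 ± 0.20) and 26 did not pass; adjusted over the list alone 1 fell. The median change was 0.03, while the mean was -0.01 and the test lay on the same side as the mean (camera, adjusted p = 0.95). Of 24 ovulation and luteinisation genes, VNN2, a pantetheinase, fell by 0.86, CD9, a membrane tetraspanin, fell by 0.25 and 22 did not pass; adjusted over the list alone 5 fell and 3 rose. The median change was -0.04 (camera, adjusted p = 0.31), and -0.02, -0.01, -0.02 and -0.09 without BSA 3, NEFA 1, NEFA 3 and NEFA 4. The transcription factor SOX9 changed by -0.10. CD9 lost its call with a further quantile normalization (-0.24, limma adjusted p = 0.053) and with any array left out, up to adjusted p = 0.12 without NEFA 3. VNN2 lost its call without BSA 3 and without NEFA 2, with a highest adjusted p of 0.053 without BSA 3 (limma).

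Some interferon-induced genes rose with NEFA, by amounts that differed between the NEFA arrays. OAS1Y, an antiviral oligoadenylate synthetase, went from 6.38 ± 0.20 to 8.44 ± 0.62 (limma, Benjamini-Hochberg adjusted p = 0.010), IFI27 from 8.33 ± 0.30 to 10.14 ± 0.49 and the antiviral GTPase MX1 from 7.99 ± 0.14 to 9.48 ± 0.52. IFI6 rose by 1.32 (SE 0.14), and the RNA sensor IFIH1 and the transcription factor IRF7 rose by 1.31 and 0.66. Of 14 matched members, these 6 rose, none fell and 8 did not pass, and adjusted over the list alone 12 rose. The listed DDX58 carries the symbol RIGI here and was not matched, so it is not among the 14. RIGI rose by 0.73 (limma, adjusted p = 0.046). ISG15 was 6.32 ± 0.41 with BSA and 8.31 ± 0.91 with NEFA and missed the threshold (limma, adjusted p = 0.055). The list was higher, with a median change of 1.19 (camera, adjusted p = 1.07e-10), but its members varied together (adjusted p = 0.14 with an estimated correlation, which was 0.74). The list mean was 5.15, 5.04, 5.28 and 5.12 on BSA 1, 2, 3 and 4, and 6.21, 6.28, 6.79 and 5.64 on NEFA 1, 2, 3 and 4. MX1 and IFIH1 lost their calls without 4 and 6 of the arrays, with highest adjusted p of 0.058 and 0.067, both without NEFA 2 (limma).

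**Figure D2:**
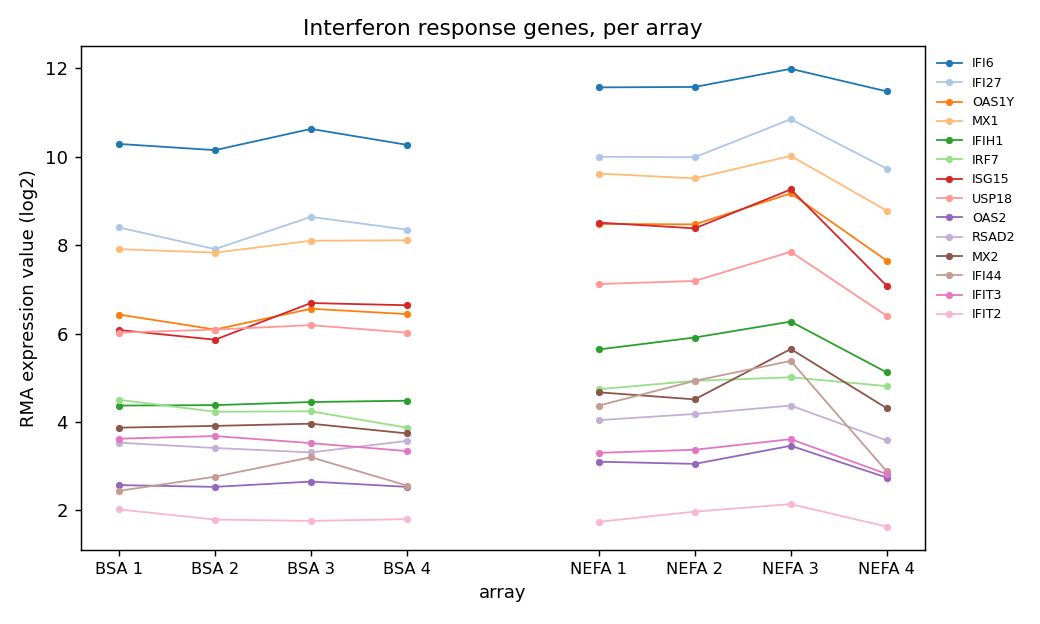
Log2 expression of 14 interferon response genes on the 8 arrays; each colour is 1 gene, and lines join its values within a group and imply no order of replicates. Among NEFA arrays, NEFA 3 was highest for 14 of 14 genes and NEFA 4 lowest for 13 of 14, and all NEFA arrays lay above all BSA arrays for 11 of 14.

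Of 24 inflammatory signalling genes, VCAM1, an adhesion molecule, rose by 0.42 (7.37 ± 0.07 to 7.80 ± 0.06) and 23 did not pass; adjusted over the list alone 1 rose. The list passed as higher with a median change of 0.15 (camera, adjusted p = 0.0061, and 0.089 with an estimated correlation). That median was 0.08 without NEFA 4 and 0.26 at its highest over the alternatives. Its median level was 3.03, which is in the dim range of the arrays.

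Most genes of the endoplasmic reticulum and integrated stress response had lower values, but few passed. HERPUD1, of protein degradation at the endoplasmic reticulum, fell by 0.33 (9.69 ± 0.01 to 9.37 ± 0.08), while the stress transcription factor DDIT3 changed by 0.07 and did not pass. Of 26 measured genes 1 fell, none rose and 25 did not pass; adjusted over the list alone 5 fell. Values were lower for 23 of 26, with a median change of -0.14 (camera, adjusted p = 5.60e-05; adjusted p = 0.13 with an estimated correlation). Of the glycolysis and hypoxia genes few passed. The glucose transporter SLC2A1 fell by 0.50 (9.02 ± 0.06 to 8.52 ± 0.08; limma, Benjamini-Hochberg adjusted p = 0.0057), the growth factor VEGFA fell by 0.50 and EGLN3, an oxygen sensor, rose by 0.34. In the glycolysis and hypoxia list, 2 of 23 fell, 1 rose and 20 did not pass; adjusted over the list alone 8 fell and 1 rose. The median change was -0.07 (camera, adjusted p = 0.0021; adjusted p = 0.13 with an estimated correlation), and -0.12 without NEFA 2. HERPUD1, VEGFA and EGLN3 each lost the call without 7 of the arrays, at adjusted p up to 0.070 without BSA 3, 0.12 without BSA 3 and 0.094 without BSA 2 (limma), and EGLN3 also with array centring (0.31, adjusted p = 0.051).

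In the respiratory chain and mitochondria list, 24 of 24 genes did not pass in limma, 21 had lower values and 6 were lower at an unadjusted p under 0.05; adjusted over the list alone none rose or fell. Its median change was -0.07 (camera, adjusted p = 0.0015; adjusted p = 0.17 with an estimated correlation), and the member of smallest p was CS, the citrate synthase, at -0.16, which passed with trend and robust eBayes alone (limma, adjusted p from 0.010 there to 0.27). Of 18 oxidative stress genes, the glutathione peroxidases GPX3 rose by 0.38 and GPX4 fell by 0.28, and 16 did not pass; adjusted over the list alone 5 rose and 2 fell. The list did not pass, with a median change of 0.01 (camera, adjusted p = 0.58), which was -0.03 with array centring. Of 18 cell death and p53 genes, TP53INP1, a p53-induced protein, rose by 0.44 (7.85 ± 0.04 to 8.29 ± 0.07), the pro-apoptotic BAX rose by 0.26 and 16 did not pass; adjusted over the list alone 5 rose. The list was higher, with a median change of 0.06 (camera, adjusted p = 0.0049, and 0.092 with an estimated correlation). That median was 0.09 without NEFA 2 or NEFA 3, and 0.026 at its lowest over the alternatives. None of 29 cell cycle genes passed in limma or adjusted over the list alone, 21 had higher values and 1 was higher at an unadjusted p under 0.05. Their median change was 0.08, or 0.03 without BSA 4 and 0.04 without NEFA 3, at the edge of the threshold (camera, adjusted p = 0.0505; adjusted p = 0.61 with an estimated correlation) and it passed in 10 of 16 alternatives other than the block, from an adjusted p of 0.0068 with a further quantile normalization. PCNA, which clamps the polymerase to DNA, changed by 0.08 and CENPF, a kinetochore protein, by 0.16. BAX lost its call without any of the 8 arrays, up to an adjusted p of 0.11 without BSA 3, and with array centring (0.23, limma adjusted p = 0.080). GPX3 and GPX4 lost theirs without 4 and 7 arrays, up to 0.058 without NEFA 2 and 0.075 without BSA 3.

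Extracellular matrix genes went in both directions. The proteoglycan DCN rose by 0.53 (9.77 ± 0.10 to 10.29 ± 0.14), MMP2, a matrix protease, by 0.52, fibronectin FN1 by 0.31 and the laminin chain LAMB1 by 0.27, while the collagen COL3A1 fell by 0.27 on the log2 scale. Of 28 genes 4 rose, 1 fell and 23 did not pass; adjusted over the list alone 4 rose and 1 fell. The list was higher, with a median change of 0.09 (camera, adjusted p = 0.0067; adjusted p = 0.39 with an estimated correlation), but did not pass with fry (adjusted p = 0.055). Without NEFA 4 the median was 0.03 and the call ended (adjusted p = 0.066, in a range from 6.88e-04 to 0.39 over the alternatives other than the block). COL3A1 and FN1 lost their calls without any of the 8 arrays, DCN without 4 and MMP2 without 6, at adjusted p up to 0.11 without BSA 3, 0.13 without NEFA 2, 0.067 without BSA 3 and 0.082 without BSA 3 (limma). FN1 also lost it with array centring (0.27, adjusted p = 0.079) and with array weights (0.30, adjusted p = 0.051). The mean of the matrix list was highest on NEFA 4, at 8.59, as was that of the smooth muscle markers, at 5.71.

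Few markers of other ovarian cells passed singly. Of 9 theca markers, COL15A1 rose by 0.57 (5.62 ± 0.08 to 6.19 ± 0.08), PDGFRA fell by 0.30 and 7 did not pass; adjusted over the list alone 3 rose and 1 fell. The median was 0.22 (camera, adjusted p = 0.040; adjusted p = 0.21 with an estimated correlation), and the call ended without BSA 1, BSA 4 or NEFA 2 (adjusted p = 0.083, 0.10 and 0.078), and without the dimmest 33.3% of probe sets (adjusted p = 0.053). Of 11 fibroblast and stroma markers, DCN rose, COL3A1 and PDGFRA fell and 8 did not pass; adjusted over the list alone 1 rose and 2 fell. The median was 0.04 and the test lay on the other side (camera, adjusted p = 0.69). Of 7 smooth muscle markers none passed in limma (3 higher at an unadjusted p under 0.05), with 1 rising adjusted over the list alone, 7 of 7 higher and a median of 0.24 (camera, adjusted p = 0.0032; adjusted p = 0.13 with an estimated correlation); MYH11 had the smallest p, at 0.42 (limma, adjusted p = 0.056), and passed in 5 of 14 alternatives other than the block, among them without BSA 2, where it stood apart (adjusted p from 0.011 there to 0.14). Of 11 endothelial markers VWF fell by 0.35 and 10 did not pass; adjusted over the list alone 1 fell, with a median of 0.01, and of 0.01 to 0.09 with an array left out (camera, adjusted p = 0.79). PDGFRA and VWF lost their calls without 8 and 7 of the arrays, at adjusted p up to 0.11 without BSA 3 for both (limma). None of 13 leukocyte, 6 erythroid, 11 oocyte and 9 epithelial markers passed in limma, and adjusted over the list alone none did. At an unadjusted p under 0.05, 2 leukocyte and 1 oocyte marker were higher, 0 erythroid markers differed, and 1 epithelial marker was higher and 1 lower. Their medians were 0.04, 0.14, 0.11 and -0.11 (camera, adjusted p = 0.41 for leukocyte, erythroid and epithelial, and 0.054 for oocyte markers, which passed in 7 of 15 alternatives other than the block), and their members of smallest p were LCP1, ALAS2, ZP3 and KRT18 with changes of 0.22, 0.28, 0.24 and 0.29. The erythroid median was 0.07 without BSA 3 or NEFA 3 and 0.08 without BSA 2 or BSA 4, and the epithelial median -0.07 without NEFA 1. Median levels of the endothelial, leukocyte, erythroid and oocyte markers were 3.33, 3.51, 3.40 and 3.08, in the dim range of the arrays.

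Of the 27 lists, 15 passed with the preset correlation, 8 as higher and 7 as lower. At that setting up to 4 lists also passed in splits of the arrays that hold no treatment contrast. With an estimated correlation 2 passed, the PPAR targets and fatty acid synthesis, and with fry 17 passed.

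**Figure D3:**
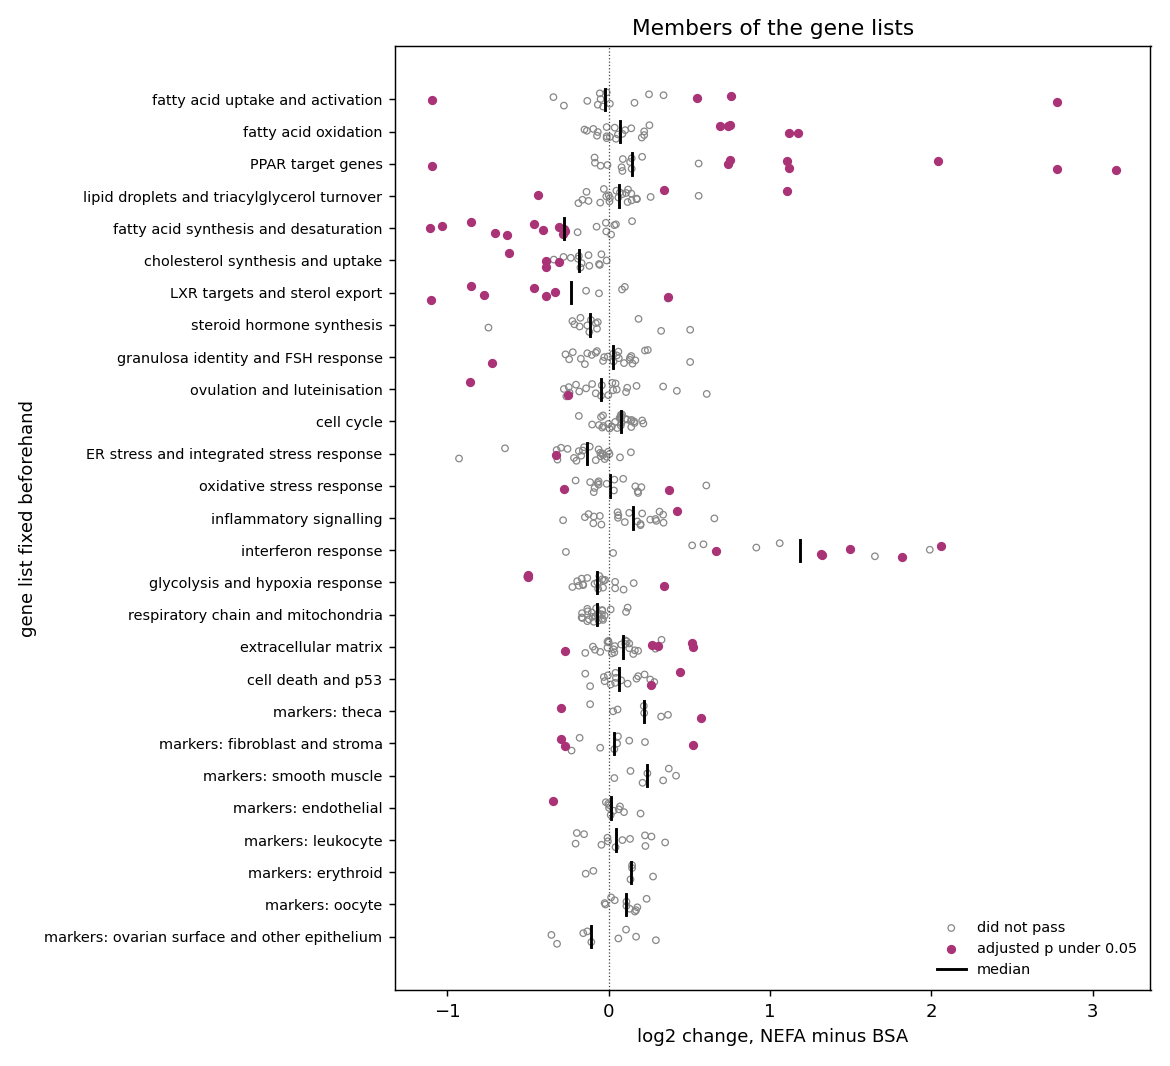
Log2 change, NEFA minus BSA, of each measured member (circle) of the 27 gene lists; filled circles passed adjusted p under 0.05 in limma and black bars are list medians. Interferon response genes had the highest median at 1.19 and fatty acid synthesis genes the lowest at -0.28.

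Among the largest changes outside the lists, PAG11, a member of the pregnancy-associated glycoproteins of the placenta, rose from 7.66 ± 0.45 to 9.54 ± 0.36 (limma, Benjamini-Hochberg adjusted p = 0.0085). LOC100298356 rose 2.83-fold. LGALS9, a galectin, rose by 1.31 on the log2 scale, SAMD9, an antiviral factor, by 1.29 and PARP12, an interferon-induced ADP-ribosyltransferase, by 1.17. COLEC12, a scavenger receptor, rose from 6.62 ± 0.08 to 7.86 ± 0.19. A second, dim probe set of LGALS9 (mean level 2.59) changed by -0.15 and did not pass. Falls included CCDC141 by 1.09, THBD, the thrombin receptor thrombomodulin, by 0.99, FGG, a fibrinogen chain, by 0.91, LOC508646 by 0.91, RNF145, a ubiquitin ligase of sterol control, by 0.90, SLC1A4, a neutral amino acid transporter, by 0.89, RASAL1 by 0.88, CADM2 by 0.85 and NPTX2 by 0.82, all on the log2 scale. The calls ended without 7 arrays for LOC508646, without 6 each for CCDC141, LOC100298356 and SAMD9, and without 3 each for LGALS9 and SLC1A4. Their highest adjusted p were 0.10 for LOC508646 and 0.082 for CCDC141 without BSA 3, 0.068 for LOC100298356 and 0.055 for SLC1A4 without NEFA 1, 0.080 for SAMD9 without BSA 4 and 0.058 for LGALS9 without NEFA 2 (limma).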

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

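The tests of interferon, fatty acid synthesis and matrix genes here were chosen only after the result was seen. The search for arrays that stand apart within a group of 4 covered 166 groups of values. It found 7, where chance gives about 1 in 20 groups, or 8.3. They were MYH11 on BSA 2 (5.16, the others 4.77 to 4.82), GPX3 on BSA 2 (9.79, the others 9.86 to 9.87), SLC2A1 on BSA 1 (9.11, the others 8.98 to 9), LOC100298356 on NEFA 4 (6.72, the others 7.67 to 7.70), VCAM1 on NEFA 1 (7.71, the others 7.82 to 7.83), KRT18 on NEFA 4 (5.14, the others 4.83 to 4.88) and HERPUD1 on NEFA 4 (9.25, the others 9.40 to 9.41).

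Interferon-induced genes were higher with NEFA, with a list median of 1.19, though 8 of 14 members did not pass and the call was lost with an estimated correlation of 0.74 (adjusted p = 0.14). Leukocytes carried into the NEFA cultures would bring their own transcripts, but the median change of their 13 markers was 0.0425 and 0 passed, with CD68 at 4.69, CD14 at 4.71 and CD74 at 3.54 on NEFA arrays. A single array did not carry the rise, since the lowest median with any NEFA array left out was 0.98. An inflammatory contaminant of the fatty acid medium cannot be told apart from an effect of the fatty acids. The inflammatory list moved by 0.15, by 0.08 without NEFA 4 and by at most 0.26 over the alternatives, and 1 of its 24 genes passed. A response of the cells to the fatty acids, or to something that came with them, stays a hypothesis that was found on these data and was not tested. The labels do not say what the replicates are, so the design cannot tell such a response from anything else shared by the arrays of a group.

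Fatty acid synthesis genes were lower with NEFA, with a median of -0.28. A drift of the normalization with signal level was tested with 10000 random lists of the same size and levels, whose lowest median was -0.135, and the list stayed below it with any array left out, so such a drift does not account for the fall. Less activity of the sterol receptor LXR may contribute, since 4 of the 10 LXR list members outside this list fell, but 1 of them, APOE, rose, and the design leaves this open. A fall of SREBF1 activity in response to the fatty acids stays a hypothesis and was not tested separately.

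Matrix genes were higher with NEFA, with a median of 0.09, but the call was lost without NEFA 4 (median 0.03), with an estimated correlation (adjusted p = 0.39) and with fry (adjusted p = 0.055). More fibroblasts would raise stromal markers alike, but 2 of the 11 fell (COL3A1 and PDGFRA) while 1 (DCN) rose. These calls were fragile, as COL3A1 and PDGFRA lost theirs with each of the 8 arrays left out and DCN with 4 of them. COL3A1 and DCN are also in the matrix list, so the markers cannot exclude more stromal cells. Level-dependent normalization cannot be told apart from a real rise, since random lists reached a median of 0.079, below that of the list with all arrays. The list median fell under it without NEFA 4, and also without BSA 4 (0.061) or NEFA 2 (0.062). More smooth muscle cells cannot be told apart from a change within the granulosa cells: their markers had a median of 0.24, with 7 of 7 higher and 0 past the threshold singly (adjusted p = 0.13 for the list with an estimated correlation), and their mean was highest on NEFA 4, as was that of the matrix list. The explanation was found from these same values, which cannot decide it, so the makeup of the cultures stays open.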

How the results depend on the processing

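The added setting, the matrix list without stromal markers, was chosen only after the result was seen; all other settings were planned. Counts are higher and lower with NEFA. Of the 63 named genes that passed, 36 passed with every array left out in turn, 23 passed in every setting, and 0 reversed. The labels do not say whether a replicate number marks a shared pool, animal or day. Correlations of same-numbered arrays' deviations were weak, at -0.01, 0.05, 0.04 and 0.07, and 2 of 4 numbers matched best. Over 4 numbers this cannot settle whether the samples are paired. With the replicate number as a block, 45 and 32 genes and 52 and 37 probe sets passed. With this block 37 of the 63 named genes lost their call, among them SCD (adjusted p = 0.051), CITED1 (0.054), MX1 (0.074), SLC2A1 (0.075) and DHCR7 (0.078), and 26 passed; 15 of 15 list calls were kept. SCARB1 had an adjusted p of 0.18 there and the oocyte markers 0.047. Leaving out the dimmest 33.3% of probe sets gave 315 and 475 genes and 371 and 534 probe sets, with fewer probe sets tested. Trend and robust eBayes gave 418 and 679 genes and 492 and 776 probe sets, and the cause was not tested. Requiring a log2 change of at least 1 left 24 and 5 genes and 32 and 10 probe sets, by construction. With an array left out, fewer samples gave 72 to 128 genes higher and 82 to 132 lower, and 86 to 153 probe sets higher and 97 to 160 lower. Further quantile normalization, array centring, array weights, the mean of a gene's probe sets and the unmoderated model kept each count within 1.5 times. Of 15 list calls, 2 were left with an estimated correlation, and the cause was not tested. The inflammatory and the cell death lists lost theirs at estimated correlations of -0.022 and 0.0095, below the preset 0.01. A higher correlation between members thus does not account for every loss. In the other settings 15 to 17 lists passed. The matrix list without stromal markers had a median of 0.10 and passed.

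Reversals concerned only results that did not pass, and the cause was not tested. With a further quantile normalization LHCGR was -0.0181, the granulosa list -0.00766 and the endothelial markers -0.0391. With array centring these were -0.0075, -0.0075 and -0.0225, and the oxidative stress list was -0.025. Without the dimmest 33.3% the stroma markers were -0.00875. With an array left out, LHCGR ran from -0.12 to 0.13, FOXL2 from -0.0675 to 0.0025, the leukocyte markers from -0.0292 to 0.0967, the uptake list from -0.0425 to 0.0121, the granulosa list from -0.0333 to 0.0408, the stroma markers from -0.0567 to 0.0233 and the oxidative stress list from -0.0129 to 0.0254. Dim probe sets limit what can be seen, as small changes near background are compressed.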

Other observations

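The splits of the arrays were planned, and the tests of the gene groups here were chosen only after the result was seen, as were the genes named. Of 33 measured genes that the transcription factor ATF4 controls 3 fell with NEFA. The amino acid transporters SLC1A4 and SLC3A2 and the proline enzyme PYCR1 fell by 0.89, 0.40 and 0.74 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.016, 0.016 and 0.027), and 31 of the 33 had lower values. Of 12 measured targets of bone morphogenetic proteins (BMPs), growth factors of the follicle, 5 fell: SMAD9 fell by 0.75, SMAD6 by 0.56, ID1 by 0.46, ATOH8 by 0.44 and ID3 by 0.28, while BMP2 itself rose by 0.66 and the BMP antagonist GREM1 by 0.43, and BMP6 fell by 0.40. Of 15 measured genes that process and present antigens 7 rose, with ERAP2 at 0.81, PSMB8 at 0.64, BOLA-NC1 at 0.53, B2M at 0.50, ERAP1 at 0.45, PSME1 at 0.44 and PSME2 at 0.43.

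Members of these groups that did not pass had a median of -0.18 over 30 ATF4 targets, -0.23 over 7 BMP targets and 0.12 over 8 antigen genes. These medians are no test of the groups, because the lists were drawn up after the pattern was seen and the change itself decides which members are left. Of the 30 ATF4 targets, 10 are also in the endoplasmic reticulum stress list.

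The order of the NEFA arrays seen in the interferon genes, highest on NEFA 3 and lowest on NEFA 4, was found in 24 of 174 other genes that rose (13.8%), in 29 of 243 that fell (11.9%) and in 8.48% of all genes, where a random order gives 8.33%. Those 24 include PARP12, PARP14, HERC5, SAMD9, RIGI, UBA7 and LGALS9. RIGI is the listed interferon gene DDX58, which was not matched to its list, so the 24 are not all independent of that list. PAG11 did not follow it, with 9.22 on NEFA 3 and 10.06 on NEFA 4. Of 19 measured genes of its family only PAG11 passed in limma, while the others changed by -0.34 to 0.21 at mean levels of at most 5.92.

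The real split gave 495 changed probe sets and 423 changed genes, and it was 1 of 35 splits in both cases, as the highest of the other splits gave 0. For gene lists 1 of 35 splits also reached the real 15, and the highest other split gave 12. By this rank the 3 counts met the planned bound of under 5% of splits, with the list count at the preset correlation. With an estimated correlation 2 lists passed. Splits with 2 arrays of each treatment on either side hold no treatment contrast. Among them, up to 4 lists still passed at the preset correlation, with 0 changed genes. A list can thus pass at that setting without a treatment contrast. The design allows no smaller share than 1 of 35, and the other splits mix both treatments, so chance is not excluded. Nor can the splits tell the treatment from anything else shared by the arrays of a group.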
